A study of Mus musculus with 23 samples.

How the data were processed

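ATAC-seq libraries came from 8 heterozygous and 13 knockout single mouse embryos of the maternal-zygotic (mz) series, collected on 1 date, and from 1 untreated and 1 tamoxifen-treated pool of the inducible series, 23 libraries in all. Groups were taken from the titles and genotype labels. Cutadapt, Bowtie2, MACS2 and the mm10 build are named per the submitters' processing notes, without versions or settings. How the authors shifted transposase insertions, removed duplicates or pooled embryos is not given in the sources used here. Duplicates left in would make reads less independent than the intervals assume, and pooling by reads would weight embryos by their depth.

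The analysed file is a single deposited table of regions bound by NR5A2 in CUT&RUN data of an earlier study, per the file headers. It holds, for each of 16958 regions, 1 ATAC-seq RPKM value per group as the authors computed it, and a CUT&RUN RPKM value. It also holds the authors' deposited ratio of knockout over control for each series, their classes of accessible and not accessible regions, their classes of change, and summit positions. The deposited ratios equalled (knockout + 0.01)/(control + 0.01) in RPKM within 5e-08 in both series. The treated pool was the numerator of the inducible ratio, whatever the order in its column name. The class of change of all 16958 regions was recovered from the arithmetic mean of both ratios, with loss under 0.667 and gain over 1.5.

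Every ATAC-seq RPKM value was a whole multiple of a single step per column, whatever the region's length, within 0.0001 of the step for 100% of values. The values were therefore not divided by the length of the listed region. Reads counted in windows of a single width, or over each region without division by its length, would both give this, and the ratios are the same either way. The step was 0.587 RPKM per read for heterozygotes, 0.359 for mz knockouts, 0.163 for the untreated and 0.170 for the treated pool, so the columns had relative depths of 1, 1.64, 3.60 and 3.45. Reads were recovered by division and rounding. Neighbouring regions may share reads if wider windows were counted. Regions with 0 reads were 2150 (12.7%), 1551 (9.15%), 231 and 369 in that order, and 3 reads, the limit that 0 allows, equalled 1.76, 1.08, 0.490 and 0.510 RPKM.

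The tests fixed before the data were examined needed values per embryo (limma or a count model for regions, exact permutation over embryos for means and classes, and a gene set test for lists). The columns hold merged groups, so none of them was run. In their place, each region's reads in the control and knockout columns were compared by a two-sided exact binomial test given the steps, with Benjamini-Hochberg adjustment over all 16958 regions at 0.05. Ratios of summed RPKM have exact (Clopper-Pearson, conditional on the sum) 95% intervals. Both cover counting error only. Contrasts between classes are log2 differences of these ratios with percentile intervals from 1000 bootstraps over regions (300 for the contrast within strata). The inducible and mz ratios of a region were compared by an exact test on the noncentral hypergeometric distribution. Log2 ratios per region used log2(RPKM + 1). The binomial test, the CUT&RUN groups, the chromosome contrasts, the read redistribution and the test between series were chosen after the table was seen.

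On simulated data, reads of the real regions were redrawn as Poisson counts with 200 regions changed by known folds. The changed regions were drawn from those at or above the median of mean RPKM in the compared columns. No shared loss and no spread between embryos were simulated. In the mz comparison 10% of regions lowered to 0.25-fold were called, 0% at 0.5-fold, 2% at 2-fold and 48% at 4-fold. In the inducible comparison the shares were 28%, 0%, 18% and 98%. Of the 16758 unchanged regions 0 were called in either. Regions with no call are therefore not shown to be unchanged.

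Regions were assigned to the nearest span of a protein-coding gene in a RefSeq gene table (GRCm38.p6, the assembly of mm10). That table gives neither strand nor exons, so transcription start sites, promoters, exons and introns could not be told, and the distance to either gene end took the place of the planned distance to a start site. No genome sequence was used, so the planned motif search was replaced by whether the authors' recentred summit, moved by up to 249 bp, differed from the original summit. Gene lists were fixed before the data were examined: inner cell mass and pluripotency, trophectoderm, primitive endoderm, 2-cell genome activation, mitosis and genome maintenance, Hippo and polarity, housekeeping, granulosa and cumulus, oocyte and maternal-effect, and liver and steroid targets of NR5A2. A list's regions lie within 50 kb of its genes. Its ratio was placed among 10000 random region sets matched on 20 strata of mean accessibility and on the accessible class, a description of these libraries and not a test of the conditions.

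Regions named in the text follow a rule fixed before the data were examined. They are up to 5 of the regions whose nearest gene is Nr5a2, the most accessible first, the 10 largest falls and 10 largest rises in RPKM between mz groups among regions at or above the median of mean accessibility, and the 2 regions of smallest p in each list. Others are said to be named after their values were seen.

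Alternatives were an adjusted p of 0.01, scaling to a median log2 ratio of 0, leaving out the least accessible regions, other pseudocounts, medians in place of sums, other distances and, added after the data were seen, scaling the summed ratio over all regions to 1, grouping regions by the other series' control, thinning of reads, a geometric mean or a pseudocount of 1 in the authors' rule, and leaving out 23 regions of mean RPKM above 20. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.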

Results

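NR5A2 is an orphan nuclear receptor that binds DNA as a transcription factor. Chromatin accessibility at regions bound by NR5A2 was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 8-cell mouse embryos with and without Nr5a2. In the maternal-zygotic (mz) series, 8 heterozygous and 13 knockout embryos were each made into a library. In the inducible series, embryos were dissected at the early 2-cell stage, 30 h after hCG, and cultured for 45 h, and 1 pool received 750 nM 4-hydroxytamoxifen for the first 24 h while 1 pool did not. The deposited table holds 16958 NR5A2-bound regions (mm10), of which the authors class 8228 as accessible and 8730 as not accessible, with 1 merged RPKM value per group and region. Whole reads recovered from these values totalled 99826 in the heterozygotes, 109296 in the mz knockouts, 285671 in the untreated pool and 190091 in the treated pool. The median region held 4 reads in each mz column, for which the exact 95% Poisson interval is 1.09 to 10.2 reads, against 14 reads in the untreated and 9 reads in the treated pool. No values of single embryos are in the table, so no difference below could be set against the spread between embryos. Every interval and test on reads compares merged libraries, not the conditions, and covers counting error only.

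The targeted gene was looked at first. No listed region lay inside the Nr5a2 gene span (chromosome 1, 136842562 to 136960448), so the table cannot check the deletion itself. The most accessible region with Nr5a2 as its nearest gene (chromosome 1, 136972880 to 136973314, 12.6 kb outside the gene) had 20.0 RPKM in heterozygotes and 15.8 RPKM in mz knockouts, and 6.86 RPKM in the untreated and 8.34 RPKM in the treated pool. Across the 5 most accessible regions with Nr5a2 as their nearest gene, which lay up to 88.0 kb away, none passed the exact binomial test in either comparison at an adjusted p of 0.05.

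The first comparison asked how accessibility at NR5A2-bound regions differs in 8-cell embryos that lack both maternal and zygotic Nr5a2. The controls were heterozygotes of the same mz series, not wild type, and their titles do not say whether they had maternal Nr5a2. Loss of the maternal and of the zygotic product can therefore not be told apart here. The accessible regions were lower in mz knockouts, with a mean of 3.61 RPKM against 5.55 RPKM in heterozygotes and a ratio of summed RPKM of 0.650 (95% interval 0.644 to 0.656). The not accessible regions had a ratio of 0.734 (0.721 to 0.747). The mean log2 ratio over accessible regions was −0.48 on the log2(RPKM + 1) scale, which understates the change of low regions. By exact binomial tests on the recovered reads with Benjamini-Hochberg adjustment over all 16958 regions, 293 regions were lower in the merged knockout library, 256 of them accessible, and 4 were higher. When the columns were scaled to a median log2 ratio of 0, a shift of −0.32, the counts became 52 lower and 7 higher. That scaling removes only part of the shared loss, since the ratio of summed RPKM over all regions was 0.668, and with this ratio scaled to 1 the counts were 14 lower and 13 higher. The table holds no open regions without NR5A2, so a lower share of reads in open chromatin as a whole was not measured.

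Among the regions with the largest loss of RPKM in mz knockouts, a region inside Got1, which encodes the cytosolic aspartate aminotransferase (chromosome 19, 43505384 to 43505906), fell from 37.6 to 6.81 RPKM (adjusted p = 9.23e-09, exact binomial test). A region inside Dnajc11, a mitochondrial J-domain protein gene (chromosome 4, 151958064 to 151958322), fell from 18.2 to 1.08 RPKM (adjusted p = 1.12e-06, exact binomial test). A region inside Hs6st1, a heparan sulfate sulfotransferase gene (chromosome 1, 36077189 to 36077563), fell from 20.6 to 2.51 RPKM (adjusted p = 1.11e-05, exact binomial test). A region 14.5 kb from Hes1, which encodes a transcriptional repressor downstream of Notch signalling (chromosome 16, 30082184 to 30082368), fell from 19.4 to 2.51 RPKM (adjusted p = 4.82e-05, exact binomial test). Regions inside Tbc1d24 and near Gm38664, Slc4a1 and Nck2 were also lower, with ratios from 0.198 to 0.266. The remaining 2 of these 10 regions lay inside Sfi1, a centrosomal protein gene, and kept the smallest relative losses, with ratios of 0.529 and 0.637. The 8 regions outside Sfi1 stayed past the threshold after scaling to the median, and the 2 Sfi1 regions did not. With the summed ratio scaled to 1, the regions at Got1, Dnajc11, Hs6st1, Hes1 and Tbc1d24 stayed past it and those near Gm38664, Slc4a1 and Nck2 did not. The regions were picked by the size of the mz difference, which favours high chance values in the heterozygote column.

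**Figure D1:**
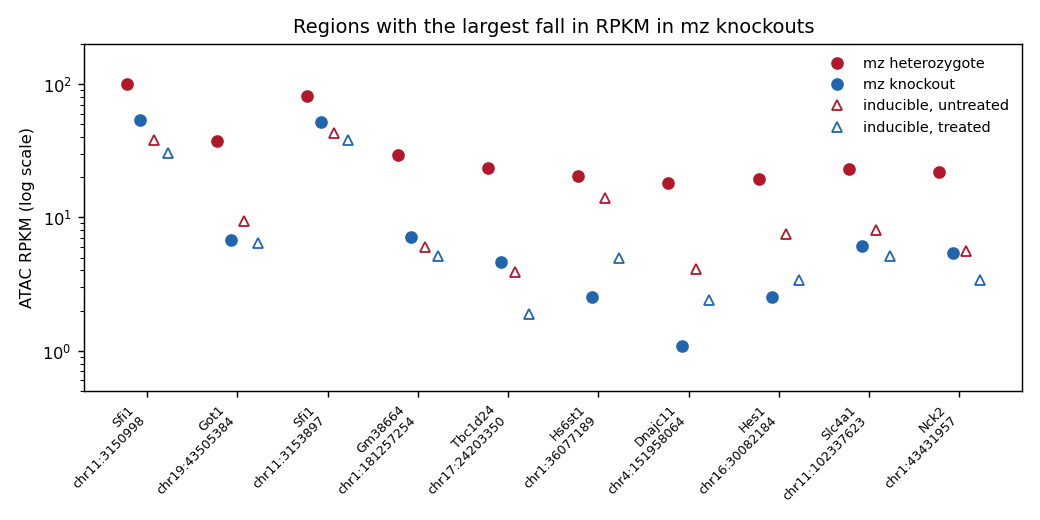
ATAC RPKM (log axis) in each merged group at the 10 regions with the largest loss of RPKM in mz knockouts, labelled by the nearest gene and the region's start; circles are the mz groups and triangles the inducible pools, red for control and blue for knockout, with 1 merged value per point and no error bars. The Hs6st1 region stands at 20.6 and 2.51 RPKM in the mz groups and at 13.9 and 4.93 RPKM in the inducible pools.

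Gains were fewer. A pair of neighbouring regions inside Sp140, a nuclear body protein gene, rose from 9.40 RPKM each to 24.0 RPKM (chromosome 1, 85591105 to 85591471, adjusted p = 0.0346, exact binomial test) and by a ratio of 2.44 (85591897 to 85592224, adjusted p = 0.0475, exact binomial test). In the inducible pools these regions had 15.5 and 19.4 RPKM, and 17.1 and 21.1 RPKM, without passing the test, although both passed in the inducible series with the summed ratio scaled to 1 (adjusted p = 0.0159 and 0.0133, exact binomial test). Of the 10 largest differences upward, 4 belonged to the Sfi1 locus and others to Lars2, Apool, Scaf8 and Mt1, and these did not pass in the mz series. The 4 Sfi1 regions, and the 2 Sfi1 regions with losses above, belong to a cluster of 12 regions with mean RPKM above 20. Together the 12 regions had a mz ratio of 0.923 (0.852 to 1.00). How reads map at such high-signal regions was not checked, so these differences are not shown to be changes of accessibility at the named genes. After scaling to the median, 4 of the 10 passed, and with the summed ratio scaled to 1, 9 of the 10. The region inside Mt1, a metallothionein gene, had a mz ratio of 1.74 (95% interval 1.03 to 3.06) and was lower in the treated pool, with a ratio of 0.537 (0.346 to 0.818), a call lost after scaling.

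Regions bound more strongly by NR5A2 in CUT&RUN, an antibody-directed cleavage assay, had lower ratios in both kinds of knockout. Over accessible regions split by the CUT&RUN signal into 5 equal-sized groups of all regions, the mz ratio went from 0.697 in the weakest group through 0.678, 0.660 and 0.633 to 0.634 in the strongest. The inducible ratio went from 0.749 through 0.713, 0.694 and 0.687 to 0.672. The strongest group was below the weakest by a log2 difference of −0.14 (region bootstrap 95% interval −0.20 to −0.07) in the mz series and −0.16 (−0.21 to −0.10) in the inducible series. Among not accessible regions the difference was −0.25 (−0.34 to −0.14) in the mz and −0.43 (−0.49 to −0.36) in the inducible series.

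**Figure D2:**
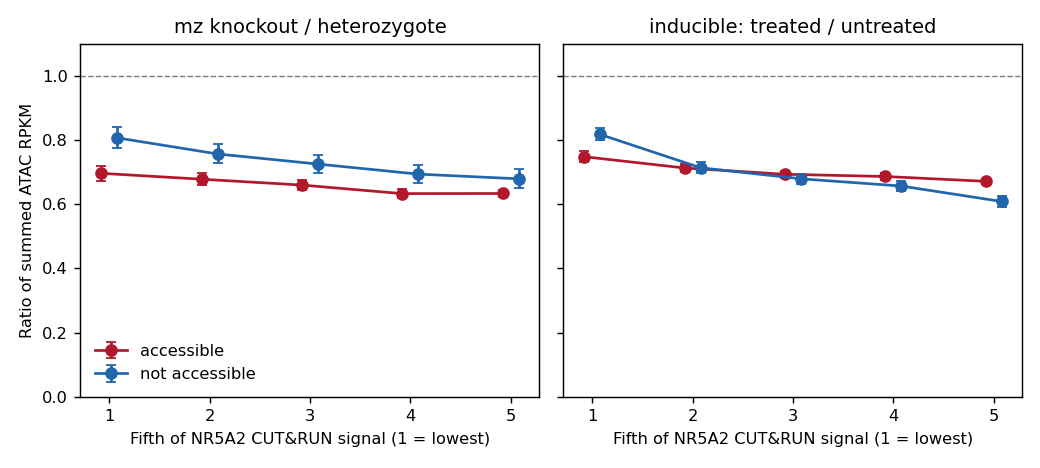
Ratio of summed ATAC RPKM, knockout over control, in 5 groups of regions ordered by NR5A2 CUT&RUN signal, for accessible (red) and not accessible (blue) regions in the mz (left) and inducible (right) series; bars are exact 95% intervals on reads. Among accessible regions the mz ratio runs from 0.697 to 0.634 and the inducible ratio from 0.749 to 0.672.

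Sequence and position classes differed as well. Accessible regions whose summit the authors had moved onto an Nr5a2 motif (7205 regions) had a mz ratio of 0.635, against 0.715 for the 1023 regions with an unmoved summit, a log2 difference of −0.17 (−0.22 to −0.12). The inducible ratios were 0.674 and 0.787, a log2 difference of −0.22 (−0.26 to −0.19). The mz difference shrank to −0.02 when medians over regions replaced summed RPKM. The 749 accessible regions within 1 kb of a gene end kept more of their accessibility than the 7479 regions farther away, with ratios of 0.768 against 0.628 in the mz series and 0.823 against 0.674 in the inducible series. These log2 differences were 0.29 (0.24 to 0.35) and 0.29 (0.25 to 0.33). The most accessible of 5 equal groups of all regions had a mz ratio of 0.655 against 0.985 in the least accessible, a log2 difference of −0.59 (−0.67 to −0.51). The inducible difference had the opposite sign, 0.15 (0.10 to 0.20), and turned to −0.17 with medians, while the mz difference was −0.57. The mean used for these groups includes the compared columns, which moves the ratios of the least accessible regions by itself. Grouped by the control of the other series, the differences were −0.23 (−0.29 to −0.16) in the mz and 0.08 (0.04 to 0.12) in the inducible series. Accessible regions on chromosome X had ratios of 0.548 in the mz and 0.568 in the inducible series, below every autosome, whose ratios ranged from 0.584 to 0.765 and from 0.654 to 0.775.

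Regions within 50 kb of inner cell mass and pluripotency genes had a mz ratio of 0.579 (0.514 to 0.652) over 81 regions, at percentile 4.96 of 10000 random region sets matched on accessibility, and within 10 kb of the genes a ratio of 0.626 at percentile 29.9. Of these regions 2 were lower and none was higher past the threshold, and adjusted over the list alone 4 were lower. The called regions lay near Klf5, which had 14.7 RPKM in heterozygotes and 3.59 RPKM in mz knockouts, and near Tfcp2l1, with 11.7 and 3.23 RPKM, both genes of pluripotency transcription factors. Regions of the trophectoderm list, genes of the outer embryonic lineage, had a ratio of 0.568 (0.485 to 0.665) over 53 regions, at percentile 7.28. A region 6.30 kb from Cdx2, the gene of a transcription factor of that lineage (chromosome 5, 147294232 to 147294973), fell from 6.46 to 0.717 RPKM (adjusted p = 0.0475, exact binomial test). A region inside Ptges, a prostaglandin E synthase gene, fell from 5.87 to 0.359 RPKM. The Cdx2 loss rested on 11 against 2 reads and the Ptges loss on 10 against 1. Neither region passed the exact test of the difference between the series. These losses were not seen in the inducible series. There the Ptges region had 0.979 RPKM untreated and 2.72 RPKM treated, and the Cdx2 region 2.29 and 2.21 RPKM, and neither passed the test. No other region of the list was called over all regions, and 5 were lower adjusted over the list alone. The 41 regions of the Hippo and polarity list had a ratio of 0.589, at percentile 18.9, and 1 region inside the polarity gene Pard3 was lower, from 6.46 to 0.717 RPKM. Adjusted over the list alone, 1 region was lower. Within 10 kb of the genes the ratio was 0.538 at percentile 5.98, and 6 regions were lower adjusted over the list alone. None of the list calls named in this paragraph stayed past the threshold after scaling to the median.

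The 20 regions near oocyte and maternal-effect genes had the lowest mz ratio of the 10 lists, 0.439 (0.360 to 0.534), at percentile 0.1. The ratio stayed between 0.411 and 0.462 with any 1 gene left out. The called regions were 3 lower, near Figla, an oocyte transcription factor gene, with 11.2 and 1.79 RPKM, inside Khdc3, a maternal-effect gene, with 16.4 and 4.66 RPKM, and near Dppa3, another maternal-effect gene, with 11.7 and 2.51 RPKM. The Figla and Khdc3 calls were lost after scaling to the median. The Dppa3 region was named after its values were seen and was not checked under that scaling. Adjusted over the list alone, 8 regions were lower. In the inducible pools the same list had a ratio of 0.760 (0.656 to 0.881), at percentile 65.7, and the difference between the series was not tested. Within 10 kb of the genes, the mz ratio was 0.503 at percentile 2.22, with 1 region called and 5 lower adjusted over the list alone. The mz median log2 ratio lay at percentile 0.7 within 50 kb and at percentile 18.8 within 10 kb.

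Regions near genes of the 2-cell stage, which are transcribed at zygotic genome activation, stood at the other end. Their 26 regions had a mz ratio of 0.982 (0.785 to 1.23) against 0.635 for the matched sets, at percentile 99.9, and an inducible ratio of 0.885 (0.780 to 1.00) against 0.674, at percentile 99.8. The mz median log2 ratio of the list was 0.10, opposite in sign to its ratio of sums. None of these regions passed the test in the mz series, also adjusted over the list alone, and the regions with the smallest p were near Tdpoz4, with 4.70 RPKM in heterozygotes and 0.717 RPKM in knockouts, and near Obox6, with 6.46 and 2.51 RPKM. With any 1 gene left out, the mz ratio lay between 0.942 and 1.08. Several of these genes have near-identical copies whose reads cannot be assigned with certainty. Over the 10 lists and both comparisons, 4 of 20 percentiles of the ratio lay outside the central 95% of the matched sets, whose regions are not clustered at a few genes as those of the lists are.

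The other lists lay within the central 95% of their matched sets in the mz series. Primitive endoderm genes had a ratio of 0.805 over 32 regions (percentile 89.3), with 0 calls over all regions and 1 lower adjusted over the list alone, and within 10 kb of the genes the ratio was 0.611 (percentile 28.1). The most extreme of them, 2.75 kb from Cited1 on chromosome X, had 5.29 RPKM in heterozygotes and 0.359 RPKM in knockouts (adjusted p = 0.0538, exact binomial test). Mitosis and genome maintenance genes had a ratio of 0.749 over 65 regions (percentile 88.4) with 0 calls, also adjusted over the list alone. Housekeeping genes had 0.696 over 37 regions (percentile 60.9), with 0 calls and 1 adjusted over the list alone, near Eef1a1 with 5.29 and 0.359 RPKM. Granulosa and cumulus cell genes, markers of the cells around the oocyte, had 0.817 over 11 regions (percentile 77.5) with 0 calls, and 0.657 (percentile 43.1) within 10 kb. The 11 regions lie near 7 of the 24 genes of the list. Gja1 holds 5 of the regions, and without this gene the ratio was 1.04. Liver and steroid target genes of NR5A2 had 0.776 over 14 regions (percentile 89.0), and 1 region 30.4 kb from Scarb1, the high-density lipoprotein receptor gene, fell from 9.40 to 1.08 RPKM (adjusted p = 0.0112, exact binomial test). The Scarb1 call was lost after scaling to the median. Only 6 of the 19 genes of this list have a region, and with any 1 gene left out its ratio lay between 0.698 and 0.937. The median log2 ratios of the primitive endoderm, 2-cell, mitosis, granulosa and liver lists lay above the median of all regions, −0.32, and those of the other 5 lists below it. Against matched sets, the housekeeping median lay at percentile 73.5 and the pluripotency median at percentile 1.21.

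**Figure D3:**
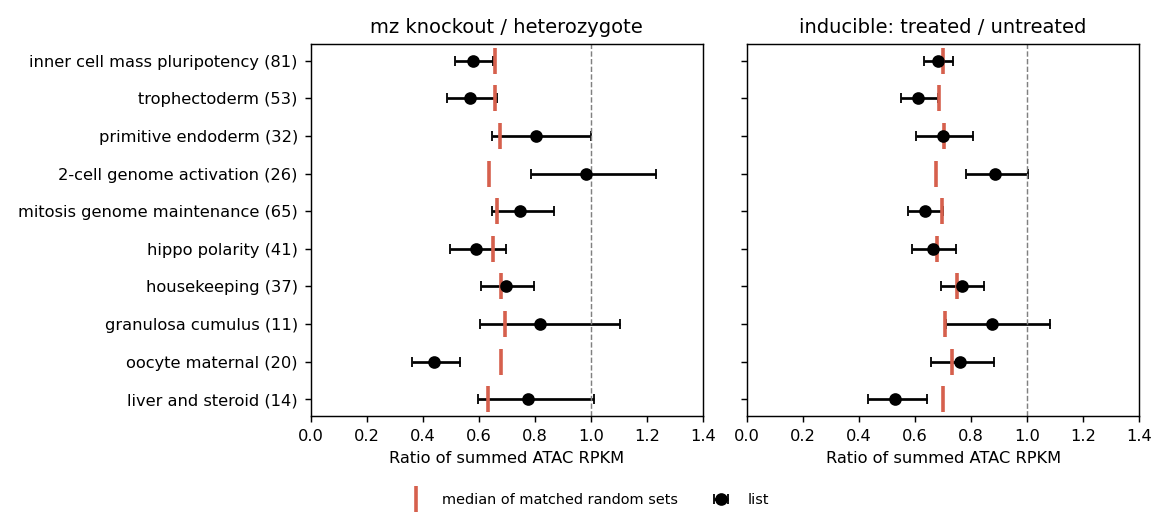
Ratio of summed ATAC RPKM over regions within 50 kb of the genes of each list (number of regions in parentheses) for the mz (left) and inducible (right) series; bars are exact 95% intervals on reads and red ticks the median of 10000 matched random region sets. The 2-cell genome activation list lies above its tick in both panels, at 0.982 and 0.885, and the oocyte list below it in the mz panel, at 0.439.

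The second comparison asked whether removal of NR5A2 from the 2-cell stage onward gives a like difference. Accessible regions were lower in the treated pool, with a mean of 2.76 RPKM against 3.98 RPKM in the untreated pool and a ratio of 0.692 (95% interval 0.687 to 0.697). The not accessible regions had a ratio of 0.698 (0.691 to 0.705). With 1 pool per arm there is no replicate check. No tamoxifen-treated pool without the deletion is among the samples, so effects of the drug and of the knockout cannot be told apart. The exact binomial test on reads found 1081 regions lower and 13 higher between these libraries, and 199 lower and 22 higher after scaling to the median, a shift of −0.35. With the summed ratio of 0.694 scaled to 1, the counts were 78 lower and 37 higher, and neither the Hs6st1 nor the Hes1 region below passed. With the reads thinned at random to the totals of the mz columns, 87 were lower and 0 higher, so the larger number of calls than in the mz series goes with the larger depth. The region inside Hs6st1 fell from 13.9 to 4.93 RPKM (adjusted p = 2.33e-04, exact binomial test), and the region near Hes1 from 7.51 to 3.40 RPKM (adjusted p = 0.0455, exact binomial test), a call that ended after scaling. The regions inside Got1, Tbc1d24 and Dnajc11 had inducible ratios of 0.683, 0.478 and 0.584 and did not pass.

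Regions of the trophectoderm list had an inducible ratio of 0.612 (0.550 to 0.681), at percentile 5.86, with 6 regions lower past the threshold and 9 lower and 1 higher adjusted over the list alone. Among them a region 787 bp from Cldn4, a tight junction gene, fell from 8.00 to 1.53 RPKM (adjusted p = 1.43e-04, exact binomial test), a region near Tead4, a transcription factor gene of that lineage, from 7.51 to 2.89 RPKM, and a region inside Cdh1, the E-cadherin gene, from 3.75 to 0.510 RPKM. Except for Chek2, whose call was lost after scaling to the median, the list regions named for the inducible series were named after their values were seen and were not checked one by one under that scaling. The pluripotency list had a ratio of 0.682 (percentile 31.5) with 4 regions lower, of which 2 were near Klf4, at 3.75 and 0.340 RPKM and at 3.75 and 0.510 RPKM, and the others near Tdgf1 and Etv5. The mitosis list had a ratio of 0.634 (percentile 8.5) with 5 regions lower, at Chek2, Cenpe, Aurka, Sgo2a and Cdc25c, and 7 lower and 1 higher adjusted over the list alone. The Hippo and polarity list had 0.664 (percentile 40.5) with 2 lower, inside Pard3 and near Pard6b.

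The liver and steroid target list had the lowest inducible ratio of the 10 lists, 0.528 (0.433 to 0.641), at percentile 1.8. Its lower regions were 2, inside Ctrl, a chymotrypsin-like protease gene, from 6.53 to 2.04 RPKM, and near Tat, the tyrosine aminotransferase gene, from 4.73 to 1.36 RPKM. Primitive endoderm genes had 0.699 (percentile 48.0) with 1 region lower, inside Col4a1. Housekeeping genes had 0.767 (percentile 63.9) with 2 lower, inside Snrpd3 and Reep5. Granulosa and cumulus genes had 0.876 (percentile 93.3) with 0 calls, and the oocyte list had 2 lower, near Sohlh1 and Uchl1. The 2-cell list had 1 region lower, inside Pdxk, and 1 higher, 34827 bp from Zfp352, from 0.979 to 3.57 RPKM (adjusted p = 0.0498, exact binomial test). Adjusted over the list alone, the housekeeping list had 1 region lower, and the pluripotency, Hippo, primitive endoderm, granulosa, oocyte, 2-cell and liver lists kept their counts. The median log2 ratios of the 2-cell, housekeeping and granulosa lists lay above the inducible median of all regions, −0.35, and those of the other 7 lists below it. Against matched sets, the median of the Hippo and polarity list lay at percentile 56.0.

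The regions that were lower in mz knockouts were also lower in the treated pool. The 293 regions had an inducible ratio of 0.552 (0.533 to 0.573), and 93.5% of them were lower in the treated pool, against 79.6% of regions of like accessibility. The 1081 regions lower in the treated pool had a mz ratio of 0.456 (0.441 to 0.471). A total of 70 regions were lower in both, where independent lists give 18.7 and independent lists within strata of like accessibility give 26.5. The series share no libraries. Across accessible regions, which are not independent replicates, the log2 ratios had Pearson's r = 0.254 and Spearman's rho = 0.244, and r = 0.131 across not accessible regions. With the accessible regions sorted by mz log2 ratio into 5 equal groups, the inducible ratio was 0.546 in the group with the largest mz loss, then 0.656, 0.719, 0.759 and 0.787. An exact test of the difference between the ratios found 3 of 16958 regions that differed, near Prkaa1, inside Pank3 and near Hspa4 (each chosen after its values were seen). At an unadjusted p under 0.05 there were 747, a share of the tested regions below 0.05, so this number does not show further differences.

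**Figure D4:**
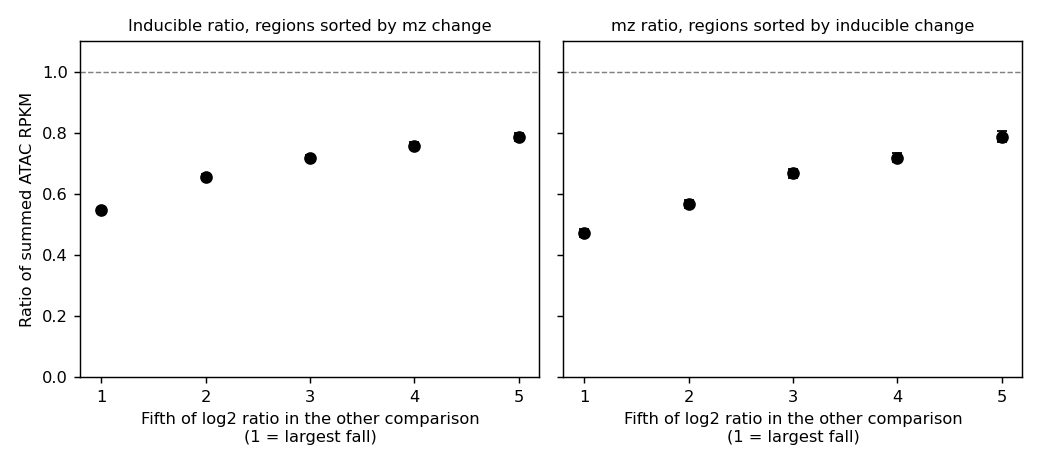
Left, inducible ratio of summed ATAC RPKM (treated over untreated) in 5 equal groups of accessible regions sorted by their mz log2 ratio; right, mz ratio in 5 groups sorted by the inducible log2 ratio; bars are exact 95% intervals on reads, mostly within the points. The inducible ratio runs from 0.546 to 0.787 and the mz ratio from 0.473 to 0.788.

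The authors' deposited table also gives each region a change class. By that table, 3813 accessible regions (46.3%) lose accessibility, 3796 are maintained and 619 (7.52%) gain it. The not accessible regions comprise 3221 losing (36.9%), 3255 maintained and 2254 gaining (25.8%). All 16958 class entries followed from the mean of the mz and inducible ratios, with losses under 0.667 and gains over 1.5. Summed over the authors' gaining accessible regions, the recovered reads gave a mz ratio of 2.67 (2.50 to 2.84) and an inducible ratio of 0.937 (0.911 to 0.964). The class was chosen by these same ratios, so a high value there is built in. The intervals do not allow for that choice, and the value is no evidence of a gain. Of the gaining regions, 177 accessible and 1437 not accessible ones had 0 reads in the heterozygote column, where 0 reads allow up to 1.76 RPKM, so their ratios rest on the added 0.01 RPKM. The class of losing regions begins near the ratio of all accessible regions, 0.650 and 0.692.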

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

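The test of the difference between the series, the CUT&RUN contrasts within strata and the weighing of the mean loss were chosen only after the results were seen, while the redistribution of reads and the chromosome X tests had their outcomes written down before they were run.

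In 3 regions the mz and inducible ratios differed by the exact test, each with the lower ratio in the mz series. A region 1711 bp from Prkaa1 had 8.22 and 0.359 RPKM in the mz groups and 3.92 and 6.47 RPKM in the inducible pools (adjusted p = 0.0352). A region inside Pank3 had 17.0 and 2.51 RPKM against 3.43 and 4.59 RPKM (adjusted p = 0.0355). A region 10977 bp from Hspa4 had 5.29 and 0 RPKM against 0.653 and 2.55 RPKM (adjusted p = 0.0355). Genotype, culture, date and pooling all differ between the series, and no explanation was tested for these regions.

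The authors' classes were set against a single loss shared by all regions of a class plus counting noise. Redistributing each region's reads 1000 times at the ratio of its class gave on average 3640.7 accessible losing regions (95% range 3555 to 3732), against 3813 observed. It gave 360.7 accessible gaining regions against 619 observed, and 1762.9 not accessible gaining regions against 2254 observed. A shared loss with counting noise alone therefore falls short of each of these counts, although with the authors' pseudocount it reaches 95.5% of the losing accessible regions and 3198 of the 3221 losing not accessible ones, and with a pseudocount of 1 only 2401 of 2978 and 1386 of 1693. Some differences between regions recurred across the series, which share no libraries. The inducible ratio ran from 0.546 to 0.787 over the groups of accessible regions sorted by mz log2 ratio. What stays open is how much of the excess may come from region-specific loss, from duplicate reads or from spread between embryos beyond counting, which merged columns cannot show.

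The larger loss at strongly bound regions was set against a change in the libraries that scales regions of like accessibility alike. This contrast took all regions, accessible or not, within 10 strata of accessibility in the other series' control. The strongest minus weakest CUT&RUN group differed by −0.176 in log2 ratio in the mz series (95% interval −0.244 to −0.115). In the inducible series it differed by −0.2864 (−0.331 to −0.244), and all 10 strata lay below 0 in both series. Scaling that is alike within these strata would give no difference. Each set of strata rests on 1 column of few reads, with a median of 14 in the untreated pool and 4 in the heterozygotes. Accessibility was therefore matched only in part, and distance to a gene end was not held constant. A change in the libraries that scales with accessibility was not excluded, and loss that depends on NR5A2 binding remains an untested hypothesis. For the mean loss itself, a lower share of reads in open chromatin in the knockout libraries and a loss of accessibility cannot be told apart, because no unbound open region is in the table. The weakest bound, not accessible regions still had a mz ratio of 0.8073 (0.776 to 0.840).

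Chromosome X had lower ratios than the autosomes in both series. If fewer X chromosomes in the knockout libraries were the source, regions that are not accessible should show it as much as accessible ones. The X to autosome ratio of ratios was 0.8558 (0.760 to 0.972) in not accessible and 0.840 in accessible regions in the mz series, and 0.7994 (0.736 to 0.867) and 0.817 in the inducible series. These values are in line with a difference in the number of X chromosomes, such as more male embryos in the knockout libraries, which may by itself lower X ratios. All regions of both classes are bound by NR5A2, so an effect of NR5A2 across X-linked regions could also give like ratios in both. Such an effect was not excluded, and the sexes of the embryos were not used here.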

How the results depend on the processing

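The thinning, the scaling of summed ratios, the pseudocount of 1, the geometric mean, the removal of high-signal regions, the contrast within strata, the groups by the other control and all alternatives of the inducible counts were chosen after the data were seen. For the values that moved, the cause was not tested unless given. At an adjusted p of 0.01, lower and higher regions numbered 66 and 0 in the mz and 344 and 0 in the inducible series, fewer by construction. Scaled to the median, they were 52 and 7, and 199 and 22, and with the summed ratio scaled to 1, 14 and 13, and 78 and 37. With reads thinned, the inducible counts were 87 and 0, by the lower depth. The mean log2 ratio over accessible regions went from −0.48 to −0.62 (pseudocount 0.1) and −0.18 (pseudocount 10) in the mz series, and from −0.46 to −0.65 and −0.13 in the inducible series, where the median was −0.42. With medians over regions, the recentred-summit difference was −0.018 (mz) and −0.17 (inducible), and the gene-end difference 0.18 and 0.21. Within 2.5 kb of a gene end it was 0.22 and 0.21, and within 0.5 kb 0.34 in the inducible series. The inducible difference between the top and bottom groups of mean accessibility reversed from 0.15 to −0.17 with medians, and the mz difference stayed at −0.57 from −0.59. Grouped by the other series' control, they were 0.077 and −0.23. The inducible CUT&RUN difference, −0.16 over accessible regions, was −0.29 within strata of all regions, so the set of regions changed as well. The correlation between series was 0.296 above the median of accessibility. With a pseudocount of 1, the authors' rule gave 1693 losing not accessible, 246 gaining accessible and 573 gaining not accessible regions. Within 10 kb in place of 50 kb, the trophectoderm list moved to percentile 1.08 in the inducible series. No other list crossed the central 95%, but the mz ratios of the primitive endoderm (0.611) and granulosa (0.657) lists went from above to below their matched sets, and the inducible ratio of primitive endoderm (0.730) from below to above.

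No paired analysis was possible because the columns hold merged groups without replicate numbers. Scaling on promoters without a motif, leaving out embryos, other motifs and an estimated gene set correlation were not run for the same reason or for lack of a genome sequence. Other size factors, quantile normalization and other region tests were not run either. With a median of 4 reads per region in each mz column, single regions carry little precision.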

Other observations

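The tests of summed ratios per gene and of high-signal regions were chosen only after the results were seen, and the genes in this part were named after their values were seen. In the series where regions were called, the summed ratio reuses the reads of those calls. That favours low ratios, which the intervals do not allow for, and adds no further evidence for the calls. Genes with several regions lower past the threshold included Thap4, with 3 of 7 regions called in the mz series and a summed mz ratio over its regions of 0.282 (0.184 to 0.423), and Hes1, with 2 of 4 regions and 0.211 (0.116 to 0.367). Both regions near Mfge8, the gene of a secreted milk fat globule protein, were called in the mz series, with a ratio of 0.122 (0.0525 to 0.253). In the inducible series, 3 of 8 regions of Cux1, a homeobox gene, were called, with ratios of 0.420 (0.302 to 0.577) in the inducible and 0.382 in the mz series. Steap3, a metalloreductase gene, had 3 of 4 regions called and ratios of 0.225 (0.139 to 0.353) and 0.285 (0.140 to 0.554). Rin2 had 3 of 5 regions called and ratios of 0.271 and 0.286. Tacc1 had 3 of 5 regions called, with an inducible ratio of 0.228 (0.135 to 0.369) and a mz ratio of 0.543 (0.259 to 1.13). Pfkfb3 had 3 of 7 regions called in the inducible series and a ratio of 0.454 (0.341 to 0.600), but a mz ratio of 0.926 (0.567 to 1.54). Sfi1 had 2 of 14 regions called in the mz series, while its regions together had a mz ratio of 0.926 (0.854 to 1.00).

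Among regions lower in both series, a region inside Optn had 11.7 and 0.717 RPKM in the mz groups and 5.71 and 0.851 RPKM in the inducible pools. A region inside Stk24 had 13.5 and 2.15 RPKM, and 6.20 and 0.510 RPKM. The 23 regions of mean RPKM above 20 had ratios of 0.935 (0.879 to 0.994) in the mz and 0.897 (0.854 to 0.942) in the inducible series. Of these regions, 12 lie at Sfi1 on chromosome 11 between 3127104 and 3181401.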
